A study of Mus musculus with 6 samples.

How the data were processed

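Total RNA was sequenced from 6 samples of 3T3L1 cells, a mouse fibroblast-like line that turns into adipocytes under hormones. Per the labels' protocols, confluent cells were induced for 2 days with dexamethasone at 1 µM, insulin at 1 µg/ml and the phosphodiesterase inhibitor IBMX at 0.5 mM, and then kept on insulin. Libraries were made with a stranded kit that removes ribosomal RNA. The labels give 3 groups of 2 samples: untreated, DMSO and LTK-14A, a compound that the labels call a butyrylation inhibitor. Its dose and the time of its addition are not given in the sources used here. The labels number the samples of each group but do not say that they came from separate cultures, so the p-values measure only the spread between these samples.

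The authors deposited 1 table of 53342 genes with Ensembl identifiers, coordinates and 1 value per gene and sample. The deposited values are on a log10 scale of a log2 scale: each is the log10 of the log2 of a normalized read count, as read from the values themselves, since no header states it. Raising 10 and then 2 to the value gave normalized values, and the commonest low value in each library was taken as 1 step. A deposited value of 0, which this formula would turn into 2, was treated as a placeholder for a normalized value of at most 1, undetected genes included, and was set to 0. The genome build was mm10, per the submitters' processing notes. The aligner, the counter, its use of strand, the annotation and the normalization method are not given in the sources used here. In the deposited table, 23.4% to 28.8% of low values lay within 0.01 of a whole step, so whole reads could not be recovered from it. No count test was therefore used, although the test planned for counts would have been one; the test planned for normalized values was used. Of the gene identifiers, 53237 were in GENCODE vM21, and 51270 had the same coordinates there.

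Depth was described by the sum of normalized values divided by the step, as a stand-in for the number of reads. This gave 5340902 and 6385677 steps in the untreated libraries, 2854171 and 2807676 in the DMSO libraries, and 3571861 and 2738411 in the LTK-14A libraries. The floor of 1 lay below 1 step in each library. Because reads are not known, no counting interval is given.

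Values were analysed as log2(value + 1), so fold changes are on that scale and understate the change of low genes. Genes with a value of at least 1 in at least 2 samples were kept, which left 24139. All 6 samples were fitted with 3 group means in limma 3.58.1 (R 4.3.3) with a mean-variance trend and no replicate block. Each comparison was tested in both directions with Benjamini-Hochberg adjustment at 0.05. The 3 comparisons were LTK-14A against DMSO, DMSO against untreated and LTK-14A against untreated. Of 39 gene lists fixed before the data were examined, 37 had at least 5 tested genes. The list of mitochondrially encoded genes had none in the table, and the epithelial list had 3, of which none passed in LTK-14A against DMSO. Lists were tested with limma's camera with a preset correlation of 0.01, again with an estimated correlation, and with fry. The estimated version takes its p from the few residual degrees of freedom of the 6 samples. A call lost with it thus need not come from correlation between genes. Camera sets a list against the other genes, while fry tests the list by itself. Agreement between comparisons that share libraries was set beside 100 simulated draws without any effect.

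Genes to be named were chosen by a rule also fixed before the data were examined. For LTK-14A against DMSO it took a panel of 24 genes, plus the 8 largest rises and 8 largest falls among genes past the threshold, with separate groups and a mean of at least 5 in the higher group. The other comparisons used 10 genes of the panel and the 5 largest in each direction, filled by the smallest p where fewer passed. Unnamed gene models, microRNA and small nucleolar genes, genes named Rn and pseudogenes were passed over. From each list described, 2 to 4 members with the smallest adjusted p were named, and some members that this gives are not reported here.

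The steps were tested on simulated libraries for LTK-14A against DMSO with 23220 genes, of which 200 were changed. The fit recovered 85 of 100 genes changed 4-fold and 47 of 100 changed 2-fold, with 0 calls among unchanged genes. The changed genes were drawn from those with a mean of at least 20, and all libraries had the same spread at a given level. Recovery of lower genes and the effect of a deviating library were thus not tested. Alternatives tried were quantile normalization, limma without the trend, no filter, a pseudocount of 0.1, a replicate block, the 2 compared groups alone, each library left out, and a 2-fold minimum. After the data were seen, a filter on a mean of at least 20 and a scaling without ribosomal and small RNA loci were added, and lists and overlap were rerun without each library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the remaining steps.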

Results

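The study measured the transcriptome of 3T3L1 cells that were differentiated into adipocytes without any addition, with the solvent DMSO, or with LTK-14A, with 2 samples in each group. The table listed 21550 to 22289 genes above a normalized value of 1 per library, and 25966 genes were at 0 in all 6 libraries. Summed normalized values ranged from 6122687 to 7091007 per library. Over 13179 genes with a mean of at least 20, the correlation between replicates, across genes, was 0.981 for LTK-14A, 0.979 for DMSO and 0.960 for untreated samples. Genes are not independent replicates, so these values only describe the libraries. The LTK-14A libraries correlated with the others at 0.869 to 0.906, and the first principal component, with 69.0% of the variance, separated them from the other 4. The second, with 15.6%, set untreated replicate 2 apart. That library also had 16.4% of its total in the ribosomal RNA loci Gm26917 and Gm42418, against 8.60% to 10.7% in the other 5. The nuclear RNA Malat1 made up 3.98% and 4.3% of the total in the LTK-14A libraries, against 1.85% to 2.81% in the others. Whether the difference in Malat1 bears on other genes was not tested. For the ribosomal RNA loci, a scaling without them and small RNA loci gave 2572 changed genes for LTK-14A against DMSO, against 2548 in the main fit. It gave 6 against 6 for DMSO against untreated, and 3114 against 3103 for LTK-14A against untreated.

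**Figure D1:**
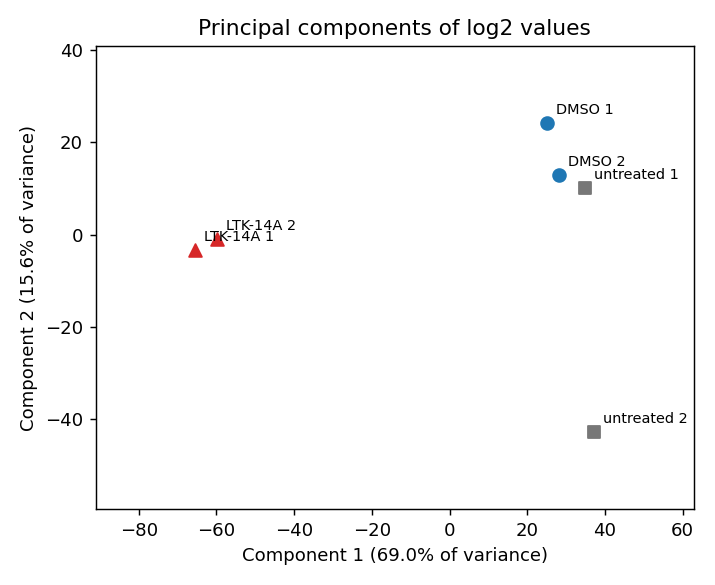
Scores of the 6 libraries on the first (x axis, 69.0% of the variance) and second (y axis, 15.6%) principal components of log2(value + 1), 1 point per library and 1 colour and shape per group. Both LTK-14A libraries lie at the left, at -65.4 and -59.8, and untreated replicate 2 lies lowest, at -42.7 on the second component.

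The comparison of LTK-14A with its solvent asked how the inhibitor changes gene expression in differentiating cells. Genes that define fat cells fell with LTK-14A. Adiponectin (Adipoq, ENSMUSG00000022878, chromosome 16, 23146536 to 23158028 in mm10), an adipocyte hormone, had 5506 ± 200 normalized counts with DMSO and 287 ± 18.8 with LTK-14A (mean ± SD, n = 2), a log2 fold change of -4.26 (SE 0.16, adjusted p = 2.6e-05, limma). Complement factor D, or adipsin (Cfd, ENSMUSG00000061780, chromosome 10, 79890853 to 79892655), had 1913 ± 24.4 with DMSO and 3.32 ± 1.76 with LTK-14A, the largest fall among the genes named (log2 fold change -8.85, SE 0.27). Of 47 ribosomal protein genes, 33 rose, with a list median of 0.914, but the call of this list was lost with an estimated correlation (adjusted p = 0.135). In all, 2548 of 24139 genes changed, 960 higher and 1588 lower. This split moved with the setting, to 1077 higher and 1274 lower after quantile normalization and 352 and 853 without the variance trend.

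Among adipogenic transcription factors, 13 of 24 fell and 0 rose (14 fell and 1 rose adjusted over the list alone). Pparg (ENSMUSG00000000440, chromosome 6, 115360951 to 115490399), the nuclear receptor that drives adipogenesis, went from 1508 ± 52.9 with DMSO to 479 ± 18.3 with LTK-14A, and fell by 1.65 on the log2 scale (SE 0.15, adjusted p = 0.000766). Cebpa (ENSMUSG00000034957, chromosome 7, 35119293 to 35121928), its partner in terminal differentiation, went from 2195 ± 65.5 to 159 ± 17.6 and fell by 3.78. The early factors Cebpb and Cebpd did not pass the threshold, with log2 fold changes of -0.30 (SE 0.19, adjusted p = 0.396) and 0.55 (SE 0.24, adjusted p = 0.195). Cebpb had an adjusted p of 0.0449 without untreated replicate 1, 0.0472 without untreated replicate 2 and 0.0475 in a fit of the 2 groups alone. Its adjusted p thus depended on the untreated libraries that entered the fit. Klf15 and Nr1h3, the liver X receptor alpha, fell with log2 fold changes of -3.79 and -3.05.

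**Figure D2:**
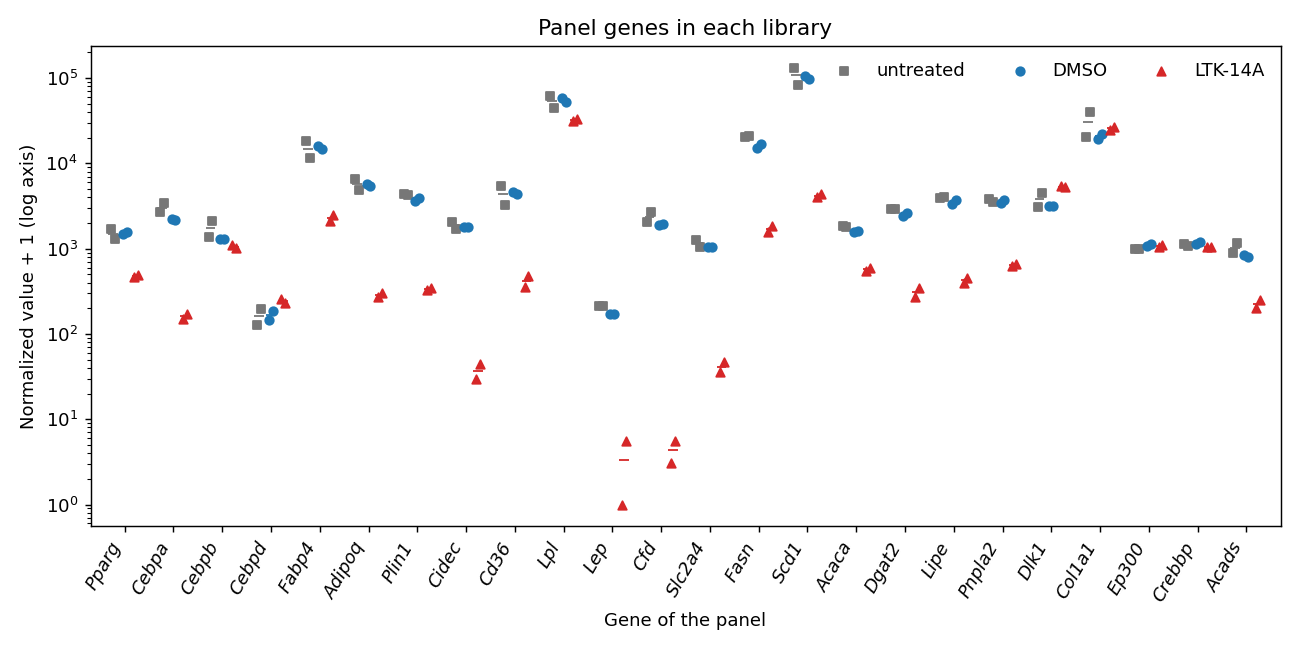
Normalized value + 1 (y axis, log scale) of the 24 panel genes (x axis) in each library, with untreated as grey squares, DMSO as blue circles and LTK-14A as red triangles; short lines are group means. Adipoq lies at 5506 with DMSO and 287 with LTK-14A, while Ep300 lies at 1100 and 1081.

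Of 40 markers of mature adipocytes, 37 fell and 0 rose (37 fell adjusted over the list alone), with a median log2 fold change of -3.00. Cidec, a protein of the lipid droplet surface, fell by 5.64 (SE 0.20). The log2 fold changes were -3.49 for Plin1, the coat protein perilipin, -4.67 for Slc2a4, the insulin-responsive glucose transporter, and -5.93 for Retn, the hormone resistin. They were -2.74 for Fabp4, a fatty acid binding protein, and -3.43 for Cd36, a fatty acid transporter. Leptin (Lep) was at 171 and 170 in the DMSO libraries and at 0 and 4.58 in the LTK-14A libraries. Lipoprotein lipase (Lpl) had the highest level of the markers on the panel other than Scd1 and fell the least of those that passed, by 0.79 (SE 0.20, adjusted p = 0.0492), from 55437 ± 3682 to 32112 ± 1352. By limma its adjusted p was 0.142 after quantile normalization, 0.148 without the variance trend and 0.0726 with a pseudocount of 0.1. It was 0.00215 in a fit of the 2 groups alone, so it depended on the untreated libraries too. Without either DMSO or either LTK-14A library the call was lost, at log2 fold changes of -0.855 to -0.719.

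In the list of fatty acid and triglyceride synthesis, 18 of 24 fell and 0 rose (19 fell adjusted over the list alone; adjusted p of the list with an estimated correlation 0.0848). Scd1, the stearoyl-CoA desaturase, went from 101150 ± 6562 to 4174 ± 201 and fell by 4.60 (SE 0.23). The log2 fold changes were -3.24 for Fasn, the fatty acid synthase, -3.03 for Dgat2, which makes triglyceride, -1.48 for Acaca, acetyl-CoA carboxylase, -2.89 for Lpin1 and -5.82 for Thrsp. In the list of lipolysis and lipid droplets, 9 of 17 fell and 0 rose (13 fell and 1 rose adjusted over the list alone; adjusted p of the list with an estimated correlation 0.0972), among them the lipase genes Mgll (log2 fold change -5.10), Lipe (-3.06) and Pnpla2 (-2.50) and the lipase inhibitor gene G0s2 (-4.86). In cholesterol synthesis, 12 of 25 fell and 0 rose (21 fell and 1 rose adjusted over the list alone), among them the reductase gene Dhcr7 (log2 fold change -1.79) and the thiolase gene Acat2 (-1.66). Of 23 genes of insulin and glucose signalling, 9 fell and 2 rose (11 and 4 adjusted over the list alone), with the smallest p for Slc2a4 and the phosphodiesterase gene Pde3b (log2 fold change -3.39). Of 12 thermogenic genes, 5 fell and 0 rose (6 and 1 adjusted over the list alone), such as the potassium channel gene Kcnk3 (log2 fold change -1.99) and the cytochrome oxidase subunit gene Cox7a1 (-4.39).

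In oxidative phosphorylation, 34 of 47 fell and 0 rose (44 fell adjusted over the list alone), with a median of -0.994. Atp5b, a subunit of ATP synthase, went from 7254 ± 185 to 2479 ± 58.0 (log2 fold change -1.55, SE 0.11), and Cyc1, cytochrome c1, fell by 1.69. In the TCA cycle, 20 of 23 fell and 0 rose (20 adjusted over the list alone), such as Pdhb of pyruvate dehydrogenase (log2 fold change -1.89) and Idh3a of isocitrate dehydrogenase (-2.05). In fatty acid oxidation and peroxisomes, 19 of 28 fell and 0 rose (22 adjusted over the list alone), among them catalase, Cat (log2 fold change -2.19), the carnitine transferase gene Cpt2 (-2.10) and Hadh (-1.74). In the list named butyryl-CoA metabolism, 16 of 22 fell and 0 rose (17 and 1 adjusted over the list alone). This list also holds genes of branched-chain amino acid breakdown, so it is not specific to butyryl-CoA. Log2 fold changes were -2.04 for Bcat2 and -2.61 for Bckdhb, both of that breakdown, and -1.87 for Acads, the short-chain acyl-CoA dehydrogenase on the panel. In the list of NRF2 targets and oxidative stress, 11 of 29 fell and 1 rose (14 and 2 adjusted over the list alone). Those with the smallest p were Cat and the pentose phosphate pathway genes Taldo1 (log2 fold change -1.80), Tkt (-1.35) and Pgd (-1.56). In the interferon response, 12 of 39 fell and 0 rose (18 and 1 adjusted over the list alone), with the smallest p for the guanylate-binding protein gene Gbp2 (log2 fold change -1.94) and for Ifi27 (-1.24).

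The 4 lists called upwards all lost their call with an estimated correlation (adjusted p = 0.131 to 0.477). Of 47 ribosomal protein genes, 33 rose and 0 fell (44 rose adjusted over the list alone). Rpl22 went from 518 ± 16.4 to 1033 ± 72.1 (log2 fold change 0.99, SE 0.12) and Rpl4 and Rplp0 rose by 0.94 and 0.95. Ribosomal protein genes share sequence with many pseudogenes, and 296 ribosomal protein pseudogenes in the table summed to 32991 and 32236 with DMSO and to 67916 and 61455 with LTK-14A. How reads were split between them is not known, so values of single ribosomal protein genes are uncertain. Of 28 lysosome and autophagy genes, 10 rose and 2 fell (13 and 2 adjusted over the list alone), with log2 fold changes of 1.41 for the protease gene Ctsl, 1.15 for the cholesterol transporter gene Npc1 and -1.18 for the autophagosome gene Map1lc3a. Of 41 matrix genes, 12 rose and 4 fell (14 and 5 adjusted over the list alone). Mmp2, a gelatinase, went from 12178 ± 835 to 34904 ± 1769 (log2 fold change 1.52, SE 0.18), Nid1 rose by 1.27, and Lum fell by 2.32. Of 20 smooth muscle and myofibroblast genes, 3 rose and 1 fell (7 and 1 adjusted over the list alone; 4 and 0 by limma after quantile normalization), with Ankrd1 among the risen genes and log2 fold changes of 0.53 for the actin-binding gene Cald1, 0.88 for the tropomyosin gene Tpm2 and -1.51 for the myosin gene Myh11.

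**Figure D3:**
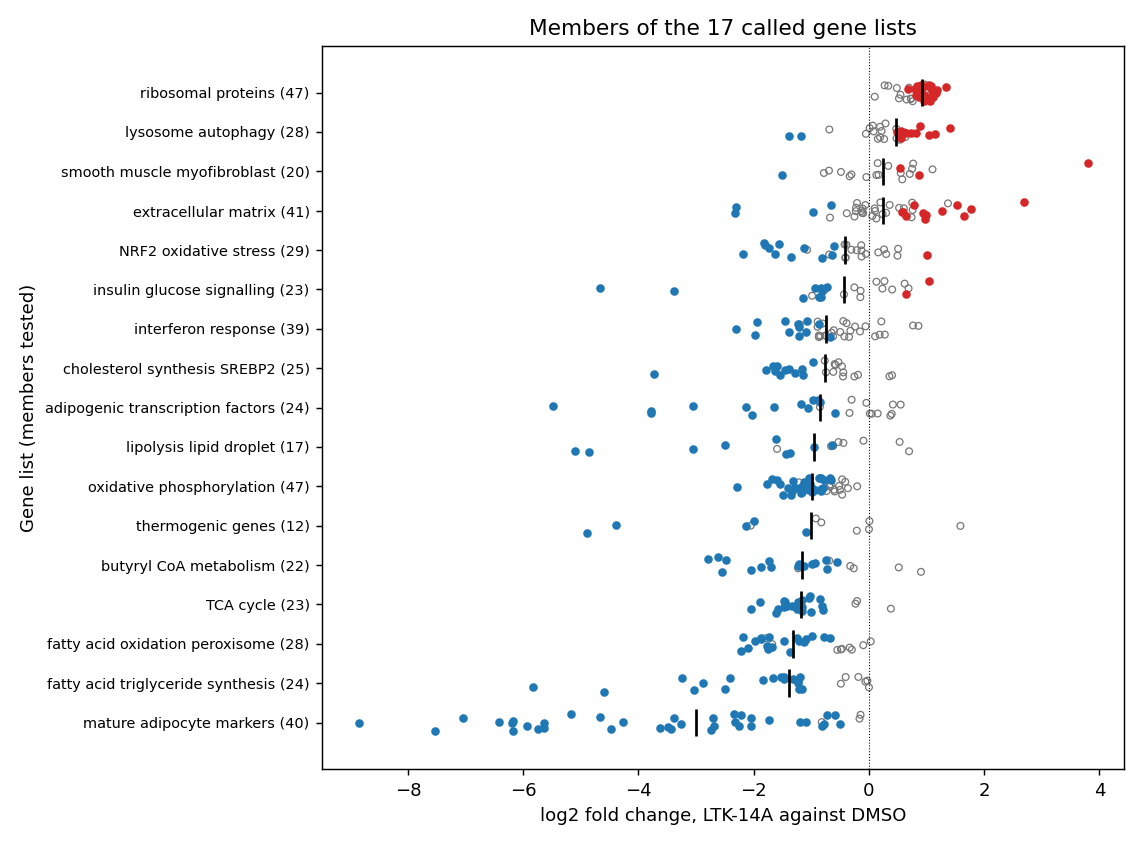
Log2 fold change of LTK-14A against DMSO (x axis) for each tested member of the 17 gene lists past the threshold (y axis, members tested in brackets), with red and blue points for genes that rose and fell, open points for genes that did not pass, and a black bar for the list's median. The median is -3.00 for mature adipocyte markers and 0.914 for ribosomal proteins.

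The largest rises named by the rule included those of the chemokine gene Ccl9 (ENSMUSG00000019122, chromosome 11, 83572919 to 83578636), from 71.6 ± 8.81 to 781 ± 155 (log2 fold change 3.42, SE 0.20), and Sorbs2, an adaptor of the cytoskeleton, from 10.6 ± 7.82 to 113 ± 0.116. The call of Sorbs2 was lost without either LTK-14A library (adjusted p = 0.0697 and 0.0635), while the call of Ccl9 held in each setting. The other 6 were low genes listed at 0 in both DMSO libraries. With LTK-14A, Myom2 stood at 19.8 and 16.0, Ankrd1 at 13.2 and 12.7, Pi16 at 7.20 and 18.3, Olfr101 at a mean of 10.2, Gprasp2 at 8.78 and 11.3, and Cd300lb at 15.1 and 4.58. In the untreated libraries these 6 lay between 0 and 4.44. Of the 6, the call of Myom2 alone held without each library. Besides Cfd, the largest falls were those of the glycerol phosphate dehydrogenase gene Gpd1, from 8755 ± 131 to 49.4 ± 24.5, Pck1, a key enzyme of gluconeogenesis, from 515 ± 45.8 to 2.94 ± 0.926, and Pnpla3, from 686 ± 6.88 to 7.28 ± 2.66. Greb1 stood at 230 and 241 with DMSO and at 3.59 and 0 with LTK-14A, Ctcflos at 124 and 174 against 0 and 1.11, and Hpx, hemopexin, at 124 and 152 against 1.87 and 0. Il2ra, at 111 and 83.5 with DMSO, was listed at 0 in both LTK-14A libraries.

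Markers of preadipocytes and fibroblasts did not pass as a list (adjusted p = 0.0615), although 6 of 27 rose and 1 fell (6 and 2 adjusted over the list alone). Fibronectin (Fn1) went from 11374 ± 96.7 to 33629 ± 498 (log2 fold change 1.56, SE 0.13), and Ddit3 rose by 1.16. Dlk1, an inhibitor of adipogenesis, rose by 0.74 (SE 0.18, adjusted p = 0.0423 by limma). Its adjusted p was 0.183 without the variance trend and 0.0659 with a pseudocount of 0.1, but 0.00116 in a fit of the 2 groups alone. Without either DMSO or either LTK-14A library the call of Dlk1 was lost, at log2 fold changes of 0.724 to 0.764. Col1a1 did not pass, at 20835 ± 1998 and 25589 ± 1759 (adjusted p = 0.572). Of 38 writers, erasers and related factors of histone acylation, 2 rose and 3 fell (3 and 4 adjusted over the list alone; list adjusted p = 0.656). The acyltransferase genes Ep300 and Crebbp did not pass, with log2 fold changes of -0.03 (SE 0.11, adjusted p = 0.925) and -0.15 (SE 0.11, adjusted p = 0.434). The histone chaperone gene Npm1 rose by 1.20, and the coactivator genes Ncoa1 and Kat2b fell with log2 fold changes of -1.40 and -0.91.

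By camera, 17 of the 37 lists passed in this comparison, 4 upwards and 13 downwards. With an estimated correlation, 4 held: oxidative phosphorylation (adjusted p = 0.0365), fatty acid oxidation, butyryl-CoA metabolism and TCA cycle (adjusted p = 0.0436 each). The other 13 did not, with an adjusted p with an estimated correlation of 0.0848 for fatty acid synthesis, 0.0972 for lipolysis and for NRF2 targets, 0.099 for mature adipocyte markers, and 0.131 for lysosome genes. It was 0.135 for adipogenic factors, for cholesterol synthesis and for ribosomal proteins, 0.145 for insulin signalling, 0.271 for thermogenic genes, and 0.477 for interferon, matrix and smooth muscle genes. Correlation between genes need not be the cause of these losses, since that version also rests on few degrees of freedom. Oxidative phosphorylation, with an estimated correlation of -0.003, below the preset 0.01, went from an unadjusted p of 6.88e-27 to 0.000986 by camera. NRF2 targets (-0.011) went from 1.82e-05 to 0.0167 and insulin signalling (0.001) from 0.00379 to 0.0508. Insulin signalling lost its call without LTK-14A replicate 2 (adjusted p = 0.0784), and smooth muscle genes lost theirs without LTK-14A replicate 1 (adjusted p = 0.0615). Samples of the 2 groups did not overlap for 54.3% of genes, where chance gives 33.3%. The count of changed genes was 677 without DMSO replicate 1, 591 without DMSO replicate 2, 644 without LTK-14A replicate 1 and 829 without LTK-14A replicate 2, each of which leaves a group with 1 library, and 1205 without the variance trend.

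The comparison of DMSO with untreated cells asked what the solvent alone does. The adipocyte genes of the panel did not differ past the threshold. Pparg was at 1508 ± 52.9 with DMSO and 1494 ± 286 without addition (log2 fold change 0.03, SE 0.15, adjusted p = 0.976), Adipoq at 5506 ± 200 and 5695 ± 1262, and Fabp4 at 15350 ± 626 and 14721 ± 4665. Cebpa was at 2195 ± 65.5 and 3019 ± 513 (log2 fold change -0.45, SE 0.15, adjusted p = 0.804) and Fasn at 16080 ± 1374 and 20452 ± 309 (-0.35, SE 0.14). Plin1, Cidec, Lep, Dlk1 and Col1a1 did not pass either, with log2 fold changes of -0.19, -0.05, -0.32, -0.23 and -0.46. Col1a1 was at -0.93 without untreated replicate 1 (adjusted p = 0.0381) and at 0.02 without untreated replicate 2 (adjusted p = 1), so its value rested on which untreated library was kept.

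In this comparison 6 genes changed, all higher with DMSO, and 1408 genes had an unadjusted p under 0.05. The glutamate transporter gene Slc1a2 (ENSMUSG00000005089, chromosome 2, 102658659 to 102790784) stood at 49.3 and 42.8 with DMSO and at 1.19 and 0 in untreated cells (adjusted p = 0.0438). Its call was lost without either DMSO library (adjusted p = 0.836 and 0.572), without either LTK-14A library (0.268 and 0.266), on the 2 groups alone (0.408), without the variance trend (0.084) and with a pseudocount of 0.1 (0.612). The other 5, which the rule passed over and which were named after their values were seen, were the gene models Gm44170, Gm45507, Gm20538, Gm29331 and Gm16567. Gm44170 (chromosome 6, 88503605 to 88504277) stood at 111 and 98.7 with DMSO and at 0 in both untreated libraries. The exons of Gm44170, Gm45507, Gm29331 and Gm16567 lie at least 97.1% inside exons of the opposite-strand genes Sec61a1, Bnip3, Adcy6 and C1s1, and the use of strand in counting is not known, so their values are uncertain. Genes with the next smallest p that did not pass were Cdr1, at 23.5 and 13.5 with DMSO and 0 in untreated libraries, Exosc6, at 15.0 and 19.2 against 0, Snhg11, at 15.0 and 11.3 against 0, and Shc4, at 47.0 ± 3.44 against 6.12 ± 0.0859. Towards lower values they were Sema3g, at 233 ± 37.3 against 473 ± 18.5, Plcl1 and Ryr1, both listed at 0 with DMSO and at 4.76 and 6.66 and at 5.29 and 4.78 in untreated cells, Col5a3, at 983 ± 0.385 against 1722 ± 417 (adjusted p = 0.0248 without untreated replicate 1 and 1 without untreated replicate 2), and Pgm2, at 706 ± 31.5 against 1026 ± 80.8.

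By camera, 13 lists passed, all towards lower values with DMSO, but 0 of the 37 held with an estimated correlation, where 4 had an unadjusted p under 0.05, and no member of any list passed alone, 0 adjusted over the list alone. The smallest adjusted p was that of glycolysis, 2.25e-08 with a median log2 fold change of -0.32 over 21 genes (adjusted p = 0.325 with an estimated correlation). Its members Gpi1, at 1855 ± 106 with DMSO and 2374 ± 51.7 in untreated cells, and Hk1, at 541 ± 11.3 and 696 ± 120, did not pass. The 13 also included mature adipocyte markers (adjusted p = 0.00833, median -0.14), fatty acid synthesis (3.79e-05, median -0.21), oxidative phosphorylation (1.51e-05, median -0.16), TCA cycle, fatty acid oxidation, butyryl-CoA metabolism and cholesterol synthesis, which were also called lower with LTK-14A against DMSO. For DMSO against untreated, their adjusted p with an estimated correlation was 0.325 to 0.621. For LTK-14A against DMSO, mature adipocyte markers, fatty acid synthesis and cholesterol synthesis also lost their call this way (camera, adjusted p = 0.099, 0.0848 and 0.135). The remaining 5 of the 13 were matrix, hypoxia, unfolded protein response, interferon and ribosomal protein genes. Of these, interferon genes were also called lower with LTK-14A against DMSO (camera, adjusted p = 2e-06, and 0.477 with an estimated correlation). Matrix and ribosomal protein genes were called higher there, and the others were not called. With DMSO against untreated, interferon genes had an adjusted p of 1.51e-05 and a median of -0.29 (adjusted p = 0.566 with an estimated correlation). Ribosomal protein genes had one of 1.51e-05 and a median of -0.22 (adjusted p = 0.516 with an estimated correlation). Without untreated replicate 2, the library with 16.4% ribosomal RNA loci, 13 lists passed, 12 lower and 1 higher, and 8 passed without DMSO replicate 1. The count of changed genes was 109 without untreated replicate 1, 6 without untreated replicate 2, 1 without DMSO replicate 2, and 0 by limma without DMSO replicate 1, LTK-14A replicate 1 or LTK-14A replicate 2, where 860, 1133 and 1130 genes had an unadjusted p under 0.05. It was also 0 by limma on the 2 groups alone, where 1182 genes had an unadjusted p under 0.05.

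The comparison of LTK-14A with untreated cells used the second reference that the design names. The adipocyte genes were again lower with LTK-14A: Adipoq fell by 4.29 (SE 0.16), and the log2 fold changes were -4.23 for Cebpa, -1.63 for Pparg, -2.64 for Fabp4, -3.67 for Plin1, -5.68 for Cidec and -3.59 for Fasn. Of the mature adipocyte markers 36 of 40 fell and 0 rose (37 fell adjusted over the list alone), of oxidative phosphorylation genes 41 of 47 fell and 0 rose (46 fell), and of ribosomal protein genes 23 of 47 rose and 0 fell (33 rose). In all, 3103 genes changed, 1130 higher and 1973 lower. Here too the split moved, to 1373 higher and 1634 lower after quantile normalization and 416 and 971 without the variance trend. The largest falls among the genes named were those of Cfd (log2 fold change -9.15), Gpd1 (-7.57), Pck1 (-7.49), Ctcflos (-6.69) and Hpx (-6.60).

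Dlk1 and Col1a1 did not pass here (adjusted p = 0.112 and 0.762). Dlk1 had a log2 fold change of 0.80 without untreated replicate 2 (adjusted p = 0.00184) and of 0.23 without untreated replicate 1 (adjusted p = 0.0957). Its adjusted p was 0.0406 with a filter on a mean of at least 20, added after the data were seen. Col1a1 was at -0.63 without untreated replicate 1 (adjusted p = 0.0113) and at 0.31 without untreated replicate 2 (adjusted p = 0.134). The largest rises were genes near or at 0 in the untreated libraries. Rmrp, the RNA of the RNase MRP complex, was at 0 in both untreated libraries and at 7197 and 6401 with LTK-14A, but also at 6113 in DMSO replicate 1 and 8.47 in DMSO replicate 2. Rmrp thus varied widely between replicates, and its listed 0 need not mean that it was absent. Its call was lost without LTK-14A replicate 1 or 2 (adjusted p = 0.122 and 0.11), without untreated replicate 2 (0.0524) and without the variance trend (0.0891). Slc1a2 stood at 64.8 and 62.7, Meg3 at 60.3 and 16.6, Cdr1 at 24.9 and 25.2 and Grin2b at 18.0 and 13.7 with LTK-14A. These 4 were also present with DMSO alone, Slc1a2 at 49.3 and 42.8, Meg3 at 35.3 and 21.4, Cdr1 at 23.5 and 13.5 and Grin2b at 11.5 and 8.01. Meg3, Cdr1 and Grin2b were at 0 in both untreated libraries. Interferon genes fell in 19 of 39 cases and rose in 0 (30 fell adjusted over the list alone), among them Gbp2 (log2 fold change -2.12) and Ifi27 (-1.32). Of 21 glycolysis genes 9 fell and 0 rose (10 and 1 adjusted over the list alone), with the smallest p for the kinase gene Pfkfb3 (log2 fold change -2.07) and for Ldha (-1.33).

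By camera, 18 lists passed, 16 lower and 2 higher, namely ribosomal proteins and lysosome genes. Matrix genes (adjusted p = 0.202) and smooth muscle genes (0.0792), called higher against DMSO, did not pass by camera against untreated cells. With an estimated correlation, 4 lists held. They were oxidative phosphorylation (adjusted p = 0.0317) and fatty acid oxidation, butyryl-CoA metabolism and TCA cycle (adjusted p = 0.0429 each). For the other called lists described here, the adjusted p by camera with an estimated correlation was 0.105 for mature adipocyte markers and 0.191 for ribosomal proteins. It was 0.17 for lysosome genes, 0.378 for interferon genes and 0.247 for glycolysis. With fry, 25 of the 37 lists had an unadjusted p under 0.05 for LTK-14A against untreated cells. The count of changed genes was 2036 and 2048 without DMSO replicate 1 or 2, 867 and 1037 without LTK-14A replicate 1 or 2, 1387 without the variance trend and 2044 on the 2 groups alone.

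Both comparisons of LTK-14A called 2110 genes in the same direction, 717 higher and 1393 lower, and 0 in opposite directions. Independent lists of these sizes would share 44.9 higher and 130 lower genes, but the comparisons are not independent, since both use the LTK-14A libraries. The 100 simulated draws without any effect, which share those libraries too, gave a mean of 0.1 shared calls. Draws without an effect hold few calls by construction. Neither figure thus tests the agreement of the calls. The covariance of log2 fold changes across genes was 0.701, against 0.140 in the simulation, and their correlation was 0.777, against 0.500. LTK-14A and untreated, each against DMSO, shared 1 call in the same direction, Gm16567, which was lower in both, where independent lists would share 0.39. Their correlation across genes was 0.295, against a simulated 0.499, and their covariance 0.175, against a simulated 0.140. The shared libraries could not be split into groups of 2, so the part of any excess that comes from them is not known. The single shared call became 27 without untreated replicate 1, and 0 without either DMSO or either LTK-14A library.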

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

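The filter on a mean of at least 20, the scaling without ribosomal and small RNA loci, and the runs of lists and overlap without each library were chosen after the data were seen. Of 39 named gene results for LTK-14A against DMSO, 28 kept their direction and side of the threshold in every setting that tested them. The same held for 12 of 20 for DMSO against untreated and 17 of 20 for LTK-14A against untreated. Genes with a mean under 20 were not tested with the filter on a mean of at least 20. Results that reversed were past the threshold neither in the fit reported nor in that setting. With each library left out, Ep300 ranged from -0.075 to 0.024 for LTK-14A against DMSO and Col1a1 from -0.633 to 0.314 for LTK-14A against untreated. For DMSO against untreated the ranges were -0.170 to 0.223 for Pparg, -0.232 to 0.426 for Fabp4, -0.259 to 0.197 for Adipoq, -0.173 to 0.083 for Cidec, -0.517 to 0.056 for Dlk1 and -0.931 to 0.016 for Col1a1. Quantile normalization reversed Col1a1 for LTK-14A against DMSO (-0.056) and Adipoq (0.055) and Cidec (0.027) for DMSO against untreated, and the total without rRNA and small RNA loci reversed Adipoq (0.013). For LTK-14A against DMSO, the 2548 calls became 1205 in limma without the trend, 1529 with at least a 2-fold change, and 591 to 3629 with each library left out; the lone sample of a group is then assumed to vary like the others, and fewer samples are tested. For LTK-14A against untreated, the 3103 calls became 1387 without the trend, 2044 with only the 2 groups compared, 1809 with at least a 2-fold change, and 867 to 4016 with each library left out. For DMSO against untreated, the 6 calls became 3 with a pseudocount of 0.1, 0 with only the 2 groups compared (1182 genes at an unadjusted p under 0.05), and 0 to 109 with each library left out. Called lists went from 17, 13 and 18 to 4, 0 and 4 with an estimated correlation (12, 4 and 11 at an unadjusted p under 0.05), and the 13 for DMSO against untreated ranged from 8 to 13 with each library left out. The overlap of 1 gene became 2 with no filter, 0 with the replicate block, and 0 to 27 with each library left out. Where construction does not show it, the cause was not tested. Differences between replicates correlated little between groups (0.167, -0.018 and 0.052 across genes). This cannot show whether equal replicate numbers mark paired samples, which the labels do not say. The replicate block gave 2635, 5 and 3269 calls and 18, 13 and 18 lists. The smaller depth of the DMSO and LTK-14A libraries, with steps of 1.80 to 2.29 normalized counts, limits what can be said of genes listed at 0.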

Other observations

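The tests of the 6 genes higher with DMSO, of the ribosomal protein genes and of the adipocyte share were chosen after the results were seen.

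Several gene groups did not pass as lists with LTK-14A against DMSO, although members changed. Among targets of TGF-beta and BMP signalling, 7 of 24 rose and 3 fell (8 and 3 adjusted over the list alone; list adjusted p = 0.0518, and 0.0454 with a replicate block). The BMP antagonist gene Grem1 rose by 1.48 log2 units and Inhba, which encodes an activin subunit, by 2.81. Among inflammatory genes and chemokines, 5 of 32 rose and 4 fell (7 and 4 adjusted over the list alone; list adjusted p = 0.641), with log2 fold changes of 3.42 for Ccl9, 1.37 for Ccl7 and -1.01 for the lipocalin gene Lcn2. Of 11 complement genes 1 rose and 4 fell (1 and 4; 0.0793), with -8.85 for Cfd and -3.44 for Cfb. Of 18 glucocorticoid targets 2 rose and 6 fell (3 and 6; 0.139), with -2.47 for Glul, glutamine synthetase, and -3.66 for Sult1a1. Of 21 glycolysis genes 2 rose and 5 fell (6 and 8; 0.472), with -1.93 for Pfkfb3 and -1.02 for Ldha. Of 40 cell cycle genes 1 rose and 6 fell (2 and 7; 0.0704), with -0.93 for the checkpoint gene Bub1b and -0.70 for the replication gene Mcm7, but 2 rose and 0 fell by limma after quantile normalization. Of 33 histone genes 0 rose and 2 fell (0 and 2; 0.0615), Hist2h2be (-2.44) and Hist2h2aa1 (-1.20).

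Stress lists also held genes that moved apart. Ddit3, which encodes the transcription factor CHOP, rose by 1.16, while Psat1 of serine synthesis and Xbp1 had log2 fold changes of -1.05 and -0.59. In the ATF4 list 2 of 24 rose and 5 fell (2 and 8 adjusted over the list alone; list adjusted p = 0.11), and in the unfolded protein response 1 of 25 rose and 2 fell (1 and 2; 0.355). Of 18 hypoxia genes 4 rose and 1 fell (4 and 2; 0.1), with 0.55 for P4ha1 and 1.05 for the peptide gene Adm. Of 18 heat shock genes 2 rose and 1 fell (2 and 1; 0.43), with -0.54 for Hspd1 and 1.17 for Hspa4l. Of 21 p53 targets 3 rose and 2 fell (4 and 2; 0.589), with 1.33 for the kinase gene Plk2 and 0.77 for Zmat3. Of 27 immediate early and cAMP genes 5 rose and 2 fell (5 and 3; 0.268), with 0.68 for Fosl2 and -1.22 for Pde4b. Of 25 Wnt genes 1 rose and 1 fell (1 and 1; 0.641), Wisp2 (1.61) and the receptor gene Fzd4 (-2.14). Of markers of other cell types, 1 of 9 macrophage genes rose, Cd68, from 15.8 ± 1.23 to 64.7 ± 3.53, and 1 fell, Lyz2, listed at 0 in both LTK-14A libraries (1 and 1; 0.355). By limma 0 of 6 endothelial genes passed (0 and 0; 0.355), 1 of 5 skeletal muscle genes fell, Des (-2.04; 0 and 1; 0.901), and 2 of 10 bone and cartilage genes rose, Spp1 (1.66) and Runx2 (0.66; 2 and 1; 0.1). The sign of the median, the mean and the test was not the same for TGF-beta, inflammatory, unfolded protein, p53 and skeletal muscle genes.

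For the joint rise of ribosomal protein genes with LTK-14A, better recovery of short transcripts is argued against by other protein-coding genes of like length. The 3779 with coding transcripts of 462 to 1699 bases had a median log2 fold change of -0.118. The 4781 with exon lengths, merged over all transcripts, of 700 to 4362 bases had one of -0.145 (95% bootstrap interval -0.161 to -0.128). Genes at the short end of these ranges were not tested apart. A shift of reads from pseudogenes to parent genes is argued against too, since the sum over both was at least 1.84 times as high in each LTK-14A library as in each DMSO library. A hypothesis is a joint rise of messenger RNAs with a 5' terminal oligopyrimidine motif, which encode much of the translation machinery. The 32 tested genes of that kind on a list written after the rise of the ribosomal protein genes and values of its members Npm1 and Vim had been seen had a median of 0.762, against -0.187 to 0.205 for the central 95% of random lists matched on mean, and 17 rose and 0 fell, Eef1a1, Eef2 and Tpt1 among them. The random lists drew genes independently, whereas the ribosomal protein list had an estimated correlation of 0.286. Their range may thus be too narrow for genes that move together. Many of the listed genes also serve translation, so a motif effect cannot be told apart from a general rise of translation genes. The values fit that hypothesis only in direction and do not show whether synthesis or stability changed.

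Of the 6 genes higher with DMSO than in untreated cells, Gm44170, Gm45507, Gm29331 and Gm16567 lie at least 90% inside exons of an opposite-strand gene with a mean of at least 300, as do 80 of 24084 other tested genes (0.33%; 49 tested genes not in GENCODE vM21 were left out). This overlap had been noticed before it was counted, and reads shared with the overlapping genes cannot be told apart from a change in the cells, since the summed normalized values of those 4 overlapping genes changed by -522 from untreated to DMSO with a 95% interval of -1548 to 503, which holds both 0 and the -299 that would offset the gain of the 4 nested genes. Of all 84 genes nested in this way, these 4 included, 7 were under 2 in both untreated libraries and over 20 in both DMSO libraries, and 0 the reverse. The median log2 fold change over the 84 was 0.148 for DMSO against untreated. Lower depth is argued against, since the DMSO means of the 6 genes would give at least 38.7 steps in the untreated libraries, which are the deeper ones. For Slc1a2, neural RNA carried into the DMSO and LTK-14A libraries cannot be told apart from a change in the cells either: of 40 neural markers on a list made after Slc1a2, Meg3 and Cdr1 had been seen, 17 (42.5%) were higher in both DMSO than in both untreated libraries, where chance gives 16.7%, and 1 was lower. Many lay near the floor, 13 were at 0 in both untreated libraries, and Snap25, at 69.9 and 57.6 with DMSO, was at 21.6 and 27.5 with LTK-14A, close to the untreated 25.5 and 13.4.

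Adipocyte marker genes fell by unequal amounts, with log2 fold changes of -0.79 for Lpl and -8.85 for Cfd. A smaller share of adipocytes with an unchanged profile would raise alike those markers of the undifferentiated cells that adipocytes lack. If adipocytes lacked the listed preadipocyte markers, the tables argue against this as the whole account. The 22 considered had a mean of at least 20. Over these, the SD of the log2 fold changes was 3.38 times the root mean square of their standard errors. Past the threshold 5 rose and 1 fell, so the fall rests on 1 gene. Fn1 was higher by 1.56 and Mest was at -1.19. If adipocytes express part of these markers, a smaller share stays open, as do a change within the undifferentiated cells and a direct effect of LTK-14A on single genes, since the samples include no undifferentiated cells.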
